A study of Mus musculus with 8 samples.

How the data were processed

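Transcript levels were measured by the authors on 8 Affymetrix whole-transcript mouse arrays. Per the labels' protocols, total RNA of bone marrow-derived mast cells was extracted with Trizol and spin columns and labelled with biotin by whole-transcript terminal labelling. The deposited values are summarized intensities on a linear scale, 1 per probe set and array. Their medians and quartiles are almost equal between arrays, so the authors had made the arrays comparable, by a method that the labels do not state. Values were taken as deposited, without further normalization, and transformed to log2 here. Array medians lay between 70.8 and 73.9 and the smallest intensity of an array between 18.0 and 18.4, so changes of genes near that floor are compressed. No value was missing.

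Of 33794 probe sets, 23521 carried 1 gene symbol, 1820 several and 8453 none, and the last 2 groups were left out of the gene comparisons. Where a gene had several probe sets (1082 of 22180 genes), the one with the highest mean level over the arrays stood for the gene. Adjusted p-values are Benjamini-Hochberg values over all 23521 probe sets with 1 symbol, and counts are per gene. Spp1, on the list of genes chosen in advance, has no probe set with a single symbol and has no value.

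The 8 arrays were grouped by maturation (IL-3, IL-3/KITL) and medium (control, B16F10, LLC, MC38), with 1 array per combination. Linear models were fitted with limma 3.58.1 in R 4.3.3. The model of maturation plus medium has 3 residual degrees of freedom and an estimated prior of 5.281, so its error holds both the variation between arrays and any interaction. It gave IL-3/KITL minus IL-3, the mean of the 3 conditioned media minus control, each conditioned medium minus control, each medium minus the mean of the other 3, and an F test of equal levels in the conditioned media. A model with an interaction of maturation with conditioned medium, with 2 residual degrees of freedom and a prior of 5.259, tested whether the response differed between maturations. A gene passed at an adjusted p under 0.05, and all limma tests are two-sided. Where an array was left out, the other array of its medium stood alone and was assumed to vary like the others. Leaving out 1 array of a medium also removes that medium from the maturation contrast.

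Named genes were chosen by a fixed rule: among genes that passed and changed the same way in every pair of arrays of the contrast, the largest log2 changes, 14 in each direction for maturation and for conditioned medium and 6 for a single medium, and 5 for the interaction and for each medium against the other conditioned media. The same-way condition was not asked of the interaction. Where fewer than 5 passed in a direction, the places were filled up to 5 with the largest changes that did not pass, said to be so. Predicted genes, RIKEN clones, LOC symbols, small RNAs, microRNAs, olfactory and vomeronasal receptors, pseudogenes and antigen receptor segments were counted but not named. Genes given as examples of a list are among the 4 members with the largest change. A fixed set of mast cell and mediator genes (Kit, Il3ra, Csf2rb, Fcer1a, Ms4a2, Hdc, Cpa3, Cma1, Mcpt4, Tpsb2, Mcpt1, Mcpt2, Vegfa, Tnf, Il6, Il13, Ccl2, Osm, Spp1 and Plau) could be named whatever their p. In addition, 41 gene lists were fixed in advance. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation rests on the residual degrees of freedom of the model (3, or 2 for the interaction). It therefore has little power here, and a list that fails it is not shown to be unchanged. The preset correlation of 0.01 is an assumption. Where the genes of a list vary together more than that, its p-value is too small. A list that passes only with the preset correlation is therefore not shown to change as a whole. List medians of single arrays were set against 10000 random lists matched on level. Overlaps between media were set against 50 simulations of unchanged arrays with shared controls.

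The models were tested on simulated data of the same shape with 100 changed genes at a log2 change of 1 and 100 at 2. They recovered 100% of these, apart from 95% at a change of 1 for the interaction. Beside the changed genes there were 10 to 26 false calls among 22180 genes. They numbered 26 for B16F10 medium, 20 between conditioned media, 19 for conditioned medium, 15 for maturation and 12 for MC38 medium. Set against the genes called, these exceed the share of false calls that the adjusted p threshold allows. The 10 for LLC medium and the 10 for the interaction do not. The simulated noise was independent between genes and arrays and took its size from the model of maturation plus medium. Recovery in the real arrays can therefore be lower: for the interaction, a change of −3.39 in Ak4 did not pass. Alternatives were quantile normalization, arrays centred on their medians, probe sets above the 40th percentile of level only, eBayes with trend and robust, the mean of all probe sets of a gene, array weights, a change of at least 1 on the log2 scale, an adjusted p under 0.1, other model terms, single maturations and leaving out each array in turn. The model of maturation plus medium compares arrays paired by medium or by maturation; the labels give no pairing by animal or culture. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.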

Results

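Transcript levels of mouse bone marrow-derived mast cells were measured on 8 Affymetrix whole-transcript arrays. Cells had been matured in 2 ways, in interleukin 3 (IL-3) or in IL-3 with Kit ligand (IL-3/KITL), the growth factor that binds the receptor Kit and is also called stem cell factor. Each kind of cell was exposed to 4 media: non-conditioned medium as the control, and the cell-free supernatants of the mouse tumour lines B16F10 (melanoma), LLC (lung carcinoma) and MC38 (colon carcinoma). Each of the 8 combinations of maturation and medium had 1 array, so there were 4 arrays per maturation and 2 per medium, without replicates within a combination. The median intensity of an array lay between 70.8 and 73.9, and the log2 levels of any pair of arrays correlated across probe sets with r between 0.988 and 0.997. The first principal component held 42.3% of the variance and separated the maturations, and the second held 17.4% and separated the controls from the conditioned arrays. The number of arrays limits the precision of every value below, and errors are standard errors (SE) from the limma model of maturation plus medium. Those of the interaction come from the model with that term, and SE over genes or markers are marked as such. Nothing in the labels says that the arrays came from separate cultures or animals, so the p-values measure only the spread between these arrays.

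Maturation with Kit ligand was compared with IL-3 alone within each of the 4 media, to ask how the growth factors used for maturation set the state of the mast cells. Most measured genes of the lists for DNA replication, mitosis and cholesterol synthesis were lower in the IL-3/KITL cells, although none of these list calls held with an estimated correlation, where the smallest adjusted p was 0.202. Mrgprb2, the mast cell receptor for basic secretagogues, was higher by 1.11 ± 0.06 on the log2 scale in the IL-3/KITL cells (n = 4 pairs of arrays), and its relatives Mrgprb13 and Mrgprb1 by 0.98 ± 0.12 and 0.94 ± 0.14. The largest increase was in Sult1a1, a phenol sulfotransferase, at 2.81-fold, followed by Il7r, the alpha chain of the interleukin 7 receptor, at 2.75-fold, and Atp6v0d2, a subunit of the vacuolar proton pump, at 2.53-fold. The repressors Bcl6 and Bach2 rose 2.10-fold and 2.0-fold, and the gene of the pro-apoptotic protein Bim, Bcl2l11, rose 2.16-fold. Csf1, which encodes macrophage colony-stimulating factor, rose 2.15-fold, the cyclic AMP phosphodiesterase Pde7b 2.22-fold, the plexin Plxna2 1.94-fold, the proton-sensing receptor Gpr65 1.92-fold and its relative Gpr132 1.84-fold. The largest decrease was in Akr1c18, a hydroxysteroid dehydrogenase, which was 8.45-fold lower in the IL-3/KITL cells. Mcpt8, a protease gene typical of basophils, was 3.95-fold lower, Cyp4a12b 3.99-fold, the histone gene H2bc12 3.87-fold, Igfbp7 3.41-fold, the mannosyltransferase gene Pigz 3.13-fold, Nt5dc2 3.04-fold and Glipr2 2.96-fold. Genes of proliferating cells made up the rest of the named decreases: Ccna2 was 3.56-fold lower, the histone chaperone Asf1b 3.24-fold, the ribonucleotide reductase subunit Rrm2 3.09-fold, the PCNA-binding factor Pclaf 3.06-fold, the topoisomerase Top2a 3.05-fold and the mitotic kinesin Kif11 2.96-fold.

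By the limma test, 2213 of 22180 genes differed between the maturations, 1234 higher and 979 lower in the IL-3/KITL cells, and 2210 of them differed the same way in all 4 media. Of these, 109 differed by at least 1 on the log2 scale. Each of the 28 genes named above kept its call when any 1 array was left out, with adjusted p-values in the full model between 8.03e-05 and 0.0076. The count itself fell to 1149 without either B16F10 array, to 1291 without either LLC array and to 1095 without either MC38 array, because the partner array then no longer counted. The change of Rrm2 was read by its brighter probe set, while the other, at a mean log2 level of 4.60, showed a change of −0.05 ± 0.06.

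**Figure D1:**
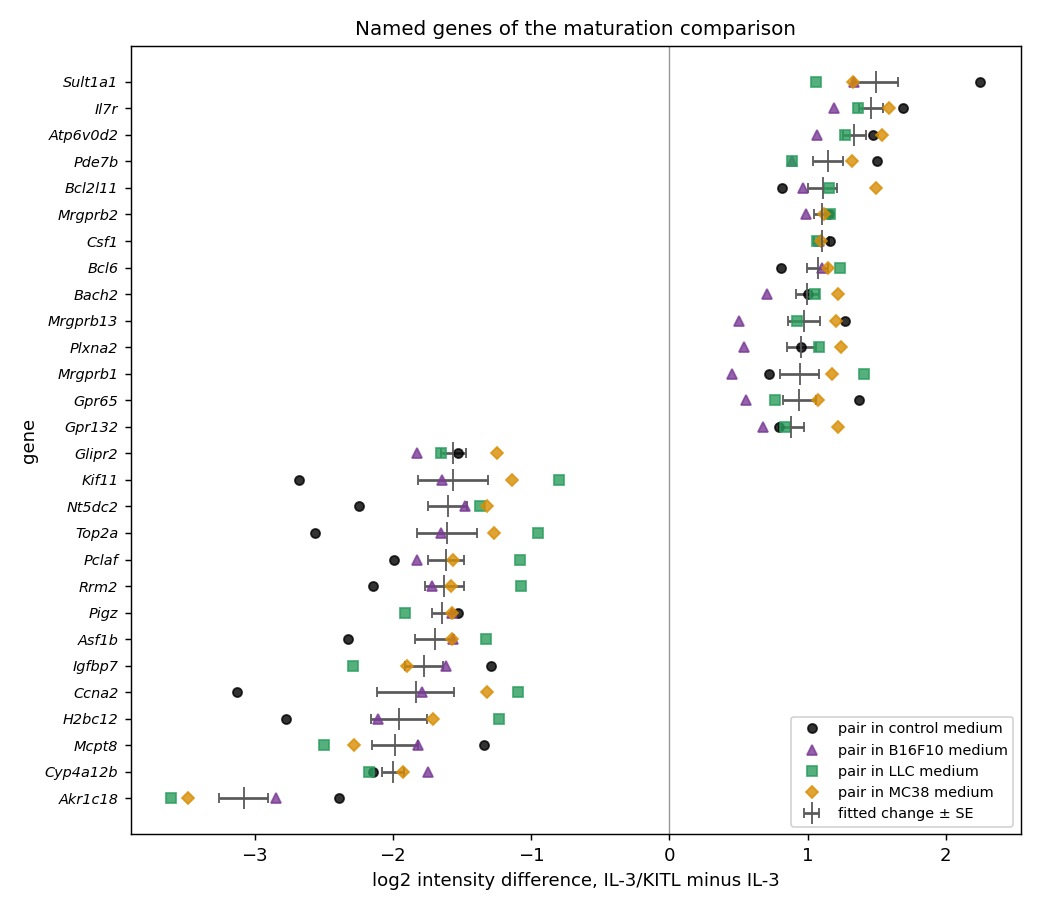
Difference in log2 intensity, IL-3/KITL minus IL-3 (horizontal axis), of the 28 named genes (vertical axis), with 1 point for the pair of arrays in each of the 4 media and a bar for the fitted change ± SE. For each gene the 4 pairs lay on the same side of 0, from Akr1c18 with a fitted change of −3.08 to Sult1a1 with 1.49.

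Among the gene lists written before the data were examined, the cell cycle lists differed most between the maturations. All 29 measured G1/S genes were lower in the IL-3/KITL cells and passed the test, with a mean change of −0.73, including the replication genes Rrm2 at −1.63 ± 0.14, Mcm5 at −1.42 ± 0.07 and Gins2 at −1.06 ± 0.06. Of the 35 measured G2/M genes, 34 fell and 1 did not pass, with a mean change of −1.09, as in Ccna2 at −1.83 ± 0.28 and Nusap1 at −1.53 ± 0.22. Adjusted over the list alone, 29 and 34 genes fell. The list test with a preset correlation gave adjusted p = 1.12e-36 for G1/S and 8.22e-31 for G2/M. With an estimated correlation, the adjusted p was 0.202 and 0.444, so neither call held there. That test, on 3 residual degrees of freedom, called 0 of the 41 lists in this comparison, so failing it decides little. Passing with the preset correlation decides little either, since its p-values are too small where the genes of a list vary together more than assumed. Of 19 cholesterol synthesis genes, 14 fell, 5 did not pass and 0 rose, and 17 fell and 1 rose when adjusted over the list alone. That list had adjusted p = 8.28e-17 with the preset correlation and adjusted p = 0.202 with an estimated correlation, so its call did not hold there. Fdps, which makes the precursor of sterols and prenyl groups, changed by −0.93 ± 0.10, and Insig1, a sensor of sterols in the endoplasmic reticulum, by −0.70 ± 0.08.

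Targets of STAT5 and of cytokine signalling were mostly lower in the IL-3/KITL cells: 12 of 20 fell, 2 rose and 6 did not pass, and 15 fell when adjusted over the list alone. Myc changed by −1.02 ± 0.12 and the feedback inhibitor Socs1 by −0.93 ± 0.07, while Bcl6 and Gfi1, both transcriptional repressors, changed by 1.07 ± 0.08 and 0.79 ± 0.07. The list had adjusted p = 2.12e-08 with the preset correlation and adjusted p = 0.202 with an estimated correlation. Of 34 genes of the ATF4 and amino acid response, 14 fell and 0 rose, and 17 fell and 2 rose when adjusted over the list alone, among them Mthfd2 of mitochondrial folate metabolism at −1.07 ± 0.14 and Psat1 of serine synthesis at −0.94 ± 0.11. This list had adjusted p = 4.43e-07, and adjusted p = 0.444 with an estimated correlation. The number of its genes that fell was 6 without either control array or either B16F10 array, 12 without either LLC array and 4 without either MC38 array. NF-kappaB targets moved the other way, with 10 of 28 that rose and 2 that fell, and 13 that rose and 2 that fell when adjusted over the list alone. Tnfaip3, an inhibitor of NF-kappaB signalling, rose by 0.88 ± 0.07 and the inhibitor Nfkbia by 0.54 ± 0.07. The list had adjusted p = 0.0075, and adjusted p = 0.444 with an estimated correlation. Its risen genes numbered 4 without either B16F10 array, 5 without either LLC array and 6 without either MC38 array, and 0, 1 and 1 fell in these fits.

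Of 27 mast cell identity genes 2 rose and 4 fell, against 2213 of all 22180 genes, and the same 2 and 4 when adjusted over the list alone, with adjusted p = 0.476 for the list and adjusted p = 0.556 with an estimated correlation. The test of fry for changes in either direction gave adjusted p = 0.0015, but it called 38 of the 41 lists, so this pass is not particular to the identity genes. Without any 1 array of a conditioned medium 0 rose and 2 fell by limma. With all arrays, Rgs13, a regulator of G protein signalling, changed by −0.48 ± 0.08 and the transcription factor gene Gata1 by −0.34 ± 0.05, and both kept their call in every such fit. Kit changed by 0.07 ± 0.06, the IgE receptor subunit Fcer1a by −0.08 ± 0.05, the carboxypeptidase Cpa3 by −0.02 ± 0.05, the chymase Cma1 by −0.06 ± 0.06 and the tryptase Tpsb2 by 0.04 ± 0.05, and none of these passed the test. Of the 20 genes of connective tissue mast cells, 5 rose, 1 fell and 14 did not pass, and 6 rose and 2 fell when adjusted over the list alone. Besides the Mas-related receptors, Ctsg, the granule protease cathepsin G, changed by −0.80 ± 0.13. The list as a whole did not pass, with adjusted p = 0.213 with the preset correlation and adjusted p = 0.529 with an estimated one. Of 7 genes of mucosal mast cells, 2 fell, with Mcpt2, a chymase of mucosal mast cells, at −0.75 ± 0.16, and 4 fell when adjusted over the list alone (adjusted p = 0.0101, and adjusted p = 0.444 with an estimated correlation). Mcpt2 did not pass without either LLC array or either MC38 array, with a change between −0.89 and −0.58 over all arrays left out in turn, and then none of the 7 genes passed. Of 31 cytokine genes, 6 fell and 2 rose, and 9 fell and 3 rose when adjusted over the list alone: Il13 changed by −1.10 ± 0.11, Osm by −0.70 ± 0.09 and Il6 by −0.61 ± 0.10, against 1.10 ± 0.05 for Csf1. The cytokine list had adjusted p = 0.0297, and adjusted p = 0.415 with an estimated correlation. The number that fell was 7 without either control array and 3 without any other array, and 1 rose in the latter fits.

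Some markers of other blood cells were also lower in the IL-3/KITL cells, beside the cell cycle genes. Of 16 markers of neutrophils and granulocyte precursors, 6 fell and 0 rose, with the granule gene Ngp at −1.04 ± 0.15 and the chemokine receptor Cxcr2 at −0.79 ± 0.12. Of 20 markers of monocytes and macrophages, 5 fell, with Ccr2 at −1.11 ± 0.09 and Adgre1 at −1.08 ± 0.10. Of 7 basophil markers, 4 fell, with Mcpt8 at −1.98 ± 0.16 and the protease Prss34 at −1.33 ± 0.16. Adjusted over the list alone, 8, 8 and 4 genes of these lists fell. The adjusted p-values were 1.29e-05, 2.28e-04 and 4.67e-04 with the preset correlation, and the adjusted p-values with an estimated correlation were 0.202, 0.255 and 0.444. Without either array of 1 conditioned medium, 2 to 3 of the neutrophil markers and 2 to 3 of the basophil markers fell, with the lowest numbers (2 of each) without the LLC arrays. Without either control array, 6 and 4 of these markers fell, as in the full model. The lists of 7 eosinophil, 10 dendritic cell, 11 T and B lymphocyte and 7 erythroid and megakaryocyte markers did not pass, with 1, 0, 1 and 1 genes that fell and 0 that rose by limma, and 2, 0, 1 and 1 that fell and 1, 0, 0 and 2 that rose when adjusted over the list alone. Their adjusted p-values were 0.240, 0.663, 0.274 and 0.910 with the preset correlation, and the adjusted p-values with an estimated correlation were 0.579, 0.743, 0.495 and 0.918. The eosinophil gene fell only with all arrays or without either LLC array, and the erythroid and megakaryocyte gene only with all arrays or without either control array, and 1 other gene of the latter list rose without either B16F10 array. HIF targets had a mean change of 0.31, with 4 of 23 that rose, 1 that fell and the same 4 and 1 when adjusted over the list alone: Ndrg1 changed by 0.62 ± 0.08 and Pfkfb3, a regulator of glycolysis, by 0.59 ± 0.09. The HIF list had adjusted p = 4.99e-04, and adjusted p = 0.529 with an estimated correlation, and without either control array its mean was 0.13 with adjusted p = 0.0624. The mean log2 level of its genes was 8.70 in the IL-3 and 9.53 in the IL-3/KITL cells in control medium, 9.15 and 9.50 in B16F10 medium, 9.06 and 9.04 in LLC medium and 8.81 and 8.90 in MC38 medium, so most of the difference lay in the control pair. Of the 41 lists, 18 passed with the preset correlation and 0 with an estimated correlation in camera, whose smallest adjusted p was 0.202. The directional test of fry, which does not compare a list with other genes, called 7.

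The 3 conditioned media together were compared with the control medium within each maturation, which asks what tumour cell supernatants in general do to these cells. In conditioned medium 12 of 19 cholesterol synthesis genes fell and 8 of 28 NF-kappaB targets rose, and 2 of each passed without the IL-3/KITL control array. Both lists had adjusted p = 0.142 with an estimated correlation. Tnfrsf9, a costimulatory receptor of the tumour necrosis factor receptor family, rose by 2.07 ± 0.07 on the log2 scale, or 4.21-fold, and each of the 6 conditioned arrays lay between 1.96 and 2.19 above the control of its maturation. The chemokine Ccl5 rose by 2.07 ± 0.17, the endosomal glycoprotein Cd68 by 1.90 ± 0.08, the cytokine Il1b by 1.69 ± 0.13 and the mast cell tryptase Tpsab1 by 1.58 ± 0.08. Insig1, a sterol sensor that is itself induced when sterols run low, fell by 1.20 ± 0.09, or 2.29-fold, in all 6 conditioned arrays. The granzyme gene Gzmc rose 3.50-fold, Arrdc4 2.56-fold, the junctional adhesion molecule gene F11r 2.28-fold, Adssl1 2.24-fold, the NADPH oxidase gene Nox1 2.15-fold, Gadd45b 2.15-fold, Gsap 2.13-fold and Pde7b 2.13-fold. Kcnma1, a potassium channel gene, was at least 7.25-fold higher on average by 1 of its 2 probe sets, mostly from the B16F10 arrays, and did not pass in LLC or MC38 medium alone. This bound takes each control array at an intensity of at least 67.1, the 40th percentile over probe sets, a floor chosen after the data were seen. The control arrays of Gzmc, at log2 levels of 5.82 and 5.73, and the conditioned arrays of Id3, at 5.53 to 5.75, also lay below that floor. Their folds are given without such a bound and are less certain. Mrgprb13 fell 2.40-fold, and the sterol synthesis or transport genes Msmo1, Cyp51, Fdps, Hmgcs1, Hsd17b7, Sqle, Stard4 and Fdft1 fell between 1.85-fold (Msmo1) and 1.47-fold (Fdft1). The transcriptional regulators Id3 and Maf fell 1.56-fold and 1.53-fold, the dehydrogenase Dhrs4 1.5-fold and the potassium channel gene Kcnj2 1.46-fold.

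By the limma test, 263 of 22180 genes differed between conditioned and control medium, 226 higher and 37 lower, and 260 differed the same way in all 6 conditioned arrays. At least 1 on the log2 scale was reached by 20 of them. The adjusted p-values of the 28 named genes lay between 1.87e-05 for Tnfrsf9 and 0.0356 for Kcnj2. The control medium rested on 2 arrays: without the IL-3 control array 44 genes passed, and without the IL-3/KITL control array 49. Without the IL-3 array of B16F10, LLC or MC38 medium the count was 146, 102 or 169, and without the IL-3/KITL array of these media 127, 129 or 141. Of the 28 named genes, 11 kept their call without any 1 array: Kcnma1, Tnfrsf9, Ccl5, Cd68, Il1b, Tpsab1, Arrdc4, F11r, Adssl1, Gadd45b and Insig1. Without the IL-3 control array 12 named genes no longer passed, with changes of 2.11 for Gzmc, 0.85 for Pde7b and −1.04 to −0.53 for Cyp51, Dhrs4, Fdft1, Fdps, Hmgcs1, Hsd17b7, Id3, Kcnj2, Sqle and Stard4. Without the IL-3/KITL control array 15 no longer passed, with changes of 0.70 for Gsap, 0.98 for Nox1, 1.5 for Gzmc and −1.07 to −0.44 for Cyp51, Dhrs4, Fdft1, Fdps, Hmgcs1, Id3, Kcnj2, Maf, Mrgprb13, Msmo1, Sqle and Stard4. Leaving out a conditioned array ended 0 to 4 of the calls of Fdps, Gzmc, Gsap, Kcnj2 and Maf, with changes of 1.70 for Gzmc, 1.05 to 1.07 for Gsap and −0.82 to −0.51 for the others. The change of Maf was read by its brighter probe set, and the other showed −0.28 ± 0.18. The control was non-conditioned medium, and no array of medium conditioned by non-tumour cells was part of these comparisons.

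**Figure D2:**
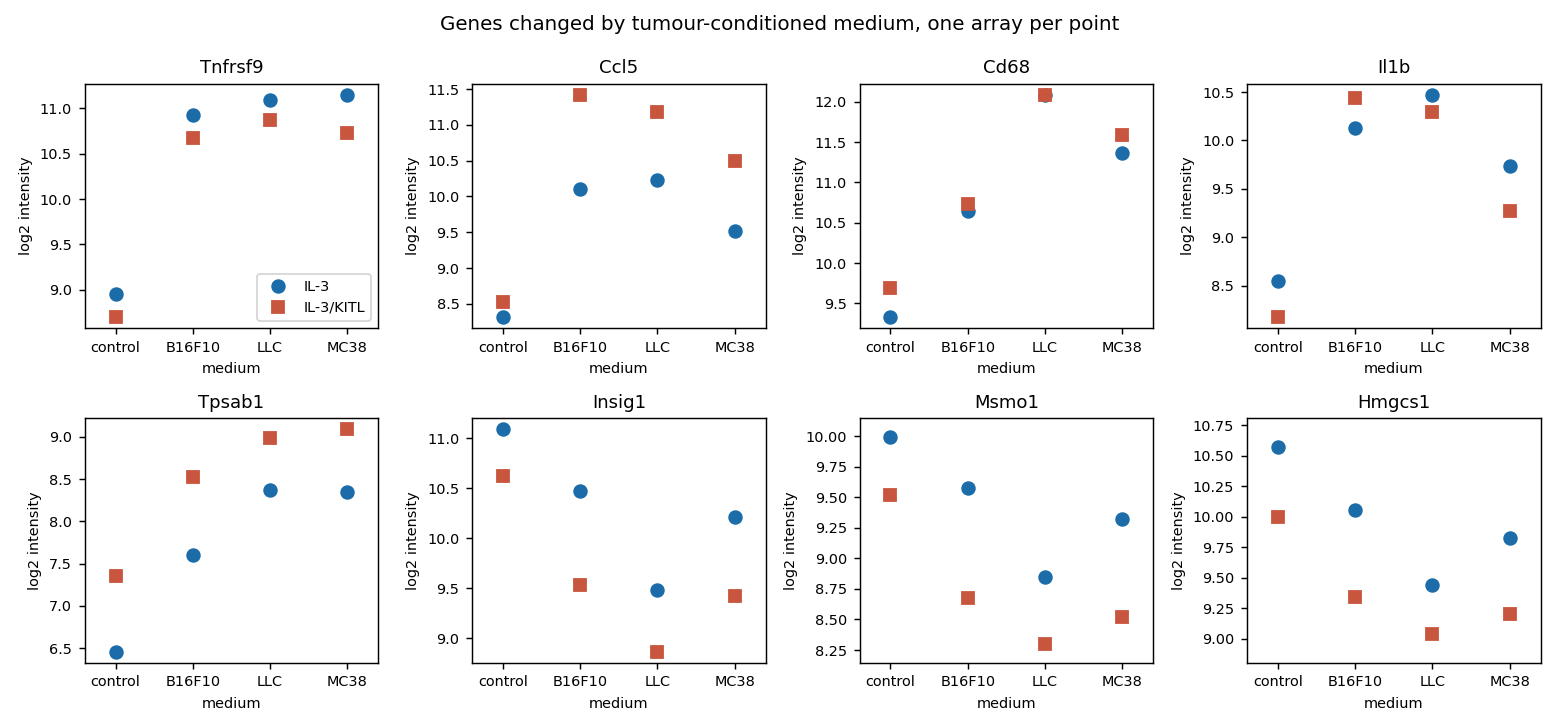
Log2 intensity per array (vertical axis) of genes that differed between conditioned and control medium, by medium (horizontal axis), with 1 point per array and 1 colour per maturation. Tnfrsf9 was 1.96 to 2.19 higher in each of the 6 conditioned arrays than in the control of the same maturation.

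Of the cholesterol synthesis genes in conditioned medium, 12 of 19 measured fell, 7 did not pass and 0 rose, 18 fell when adjusted over the list alone, and all 19 had lower estimates. The list had adjusted p = 7.57e-30 with the preset correlation and adjusted p = 0.142 with an estimated correlation. Msmo1 and Cyp51, which act on the sterol ring, changed by −0.89 ± 0.09 and −0.86 ± 0.11. Without either control array, 2 of the cholesterol synthesis genes fell, and without any other array 9 to 12 fell. Of 28 NF-kappaB targets, 8 rose, 20 did not pass and 0 fell, 20 rose when adjusted over the list alone, and 26 had higher estimates. The list had adjusted p = 4.26e-18, and adjusted p = 0.142 with an estimated correlation, so the call did not hold there. Tnip3 and Nfkbia, both inhibitors of the pathway, changed by 0.90 ± 0.07 and 0.76 ± 0.09, and Traf1, an adaptor of tumour necrosis factor receptors, by 0.86 ± 0.10. Of the NF-kappaB targets, 4 rose without the IL-3 control array and 2 without the IL-3/KITL control array, where Nfkbia and Traf1 no longer passed at 0.62 and 0.65. Without a conditioned array, 5 to 7 rose. Of 29 interferon response genes, 4 rose and 0 fell, 13 rose when adjusted over the list alone, and 25 had higher estimates, with the antiviral gene Rsad2 at 0.74 ± 0.10 and Dhx58, a cytosolic RNA sensor relative, at 0.70 ± 0.06. The list had adjusted p = 8.07e-11, and adjusted p = 0.142 with an estimated correlation. Its risen genes numbered 1 without the IL-3 control array, 0 by limma without the IL-3/KITL control array, where Rsad2 and Dhx58 no longer passed, and 2 or 3 without a conditioned array.

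Single genes of secreted and surface molecules rose in conditioned medium as well. Of 27 chemokine genes, 3 rose and 0 fell, and 8 rose when adjusted over the list alone: beside Ccl5, Ccl22 rose by 0.86 ± 0.07 and Ccl9 by 0.55 ± 0.09. Of 31 cytokine genes, 2 rose, Il1b and Il1a, the latter by 0.85 ± 0.13, and 2 rose when adjusted over the list alone. Il6 at −0.09 ± 0.12, Il13 at 0.28 ± 0.13, Tnf at 0.52 ± 0.15, Osm at 0.04 ± 0.10, Ccl2 at 0.25 ± 0.11, Vegfa at 0.33 ± 0.18 and Plau at 0.04 ± 0.08 did not pass. Of 25 immune regulatory molecules, 3 rose and 0 fell, and 4 rose when adjusted over the list alone: Tnfrsf9, the inhibitory receptor Lag3 by 0.43 ± 0.08 and the inhibitory receptor Cd200r1 by 0.38 ± 0.07. The adjusted p-values of these 3 lists were 9.16e-04, 0.0204 and 0.0010 with the preset correlation, and the adjusted p-values with an estimated correlation were 0.317, 0.292 and 0.241. Lag3 and Cd200r1 did not pass without any 1 of the 8 arrays, with changes of 0.31 to 0.55 and of 0.36 to 0.41. Ccl9 did not pass without 6 of the arrays, all but those of B16F10 medium, at 0.48 to 0.62, and Il1a without either control, the IL-3 LLC or the IL-3/KITL B16F10 array, at 0.62 to 1.08. Without the IL-3 control array the chemokine list had adjusted p = 0.0666 and the cytokine list adjusted p = 0.242.

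Of the mast cell genes, Hdc, the enzyme that makes histamine, rose by 0.47 ± 0.06 in conditioned medium, and it no longer passed without either control array or the IL-3 LLC array, at 0.46 to 0.49 over all arrays left out. It was 1 of 27 mast cell identity genes that passed, with 2 that rose and 1 that fell when adjusted over the list alone. Kit at −0.06 ± 0.06, Fcer1a at 0.00 ± 0.06, Cpa3 at 0.02 ± 0.06 and Cma1 at −0.13 ± 0.07 did not pass. Among 20 connective tissue mast cell genes, Tpsab1, Ddc and Hdc rose, Mrgprb13 fell and 16 did not pass, and 4 rose and 2 fell when adjusted over the list alone. The identity list had adjusted p = 0.486 and the connective tissue list adjusted p = 0.187 with the preset correlation, and adjusted p = 0.585 and 0.487 with an estimated correlation. Of 20 monocyte and macrophage markers, 1 rose, Cd68, and of 16 neutrophil markers 1 rose, Mmp8, by 0.71 ± 0.13. Ddc rose by 0.59 ± 0.10 and no longer passed without 6 of the arrays, all but the IL-3/KITL control and B16F10 arrays, at 0.39 to 0.78. Mmp8 passed only with all 8 arrays or without the IL-3/KITL control array, and its change lay between 0.43 and 1.0. Of the 41 lists, 13 passed with the preset correlation and 0 with an estimated correlation in camera, whose smallest adjusted p was 0.142, and fry called 6.

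Each conditioned medium was then compared with the control medium, 2 arrays against 2. In B16F10 medium 88 genes rose and 3 fell, led by Ccl5 at 5.07-fold, Gzmc at 4.21-fold, Tnfrsf9 at 3.91-fold, Il1b at 3.79-fold and Nox1 at 3.06-fold, apart from the Kcnma1 probe set. The 3 that fell were Insig1 at 1.81-fold, Id3 at 1.64-fold and Hmgcs1 at 1.5-fold; Mrgprb13 with a change of −0.97 ± 0.17 and Rps4l with −0.70 ± 0.27 did not pass. In LLC medium 251 genes rose and 74 fell: Cd68 rose 5.93-fold, Ccl5 4.86-fold, Tnfrsf9 4.43-fold, Il1b 4.05-fold, Gzmc 3.48-fold and Tpsab1 3.41-fold, while Mrgprb13 fell 3.4-fold, Insig1 3.22-fold, Msmo1 2.28-fold, Cyp51 2.22-fold, Fdps 2.15-fold and Hmgcs1 2.06-fold. In MC38 medium 49 genes rose and 9 fell: Tnfrsf9 rose 4.31-fold, Cd68 3.89-fold, Tpsab1 3.52-fold, Ccl5 3.01-fold, Pde7b 2.48-fold and the protein C receptor gene Procr 2.39-fold, while Insig1 fell 2.06-fold, Sqle 1.95-fold, Hsd17b7 1.81-fold, Msmo1 1.79-fold, Hmgcs1 1.71-fold and Dnase2b 1.61-fold. By limma, the called genes numbered 91, 325 and 58 for B16F10, LLC and MC38 medium, of which 20, 41 and 15 reached 1 on the log2 scale. Of 19 cholesterol synthesis genes, 2 fell in B16F10, 13 in LLC and 6 in MC38 medium, and 14, 18 and 17 when adjusted over the list alone. Their adjusted p-values were 2.36e-16, 1.57e-30 and 7.04e-31 with the preset correlation, and the adjusted p-values with an estimated correlation were 0.232, 0.191 and 0.160. Of 28 NF-kappaB targets, 5, 8 and 2 rose, and 19, 18 and 11 when adjusted over the list alone, with adjusted p-values of 4.38e-16, 6.45e-16 and 1.10e-13, and the adjusted p-values with an estimated correlation were 0.232, 0.191 and 0.210.

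These single-medium counts moved strongly with single arrays. The B16F10 count was 42 without the IL-3 control array, 22 without the IL-3/KITL control array, 17 without the IL-3 B16F10 array, 10 without the IL-3/KITL B16F10 array and 47 without either LLC array. The LLC count was 11 without the IL-3 LLC array, 49 without the IL-3/KITL LLC array, 119 and 86 without the IL-3 and the IL-3/KITL control array, 215 without either B16F10 array and 208 without either MC38 array. The MC38 count was 3 without the IL-3/KITL MC38 array, 18 without the IL-3 MC38 array, 18 and 10 without the IL-3 and the IL-3/KITL control array and 24 without either LLC array. The named genes that kept their call without any 1 array were Kcnma1, Tnfrsf9 and Nox1 in B16F10 medium, Cd68, Tnfrsf9, Tpsab1 and Insig1 in LLC medium, and Tnfrsf9, Cd68 and Tpsab1 in MC38 medium. The others lost it in at least 1 such fit with the same direction. In B16F10 medium these were Ccl5 without the IL-3/KITL B16F10 array, at 2.04, Il1b without the IL-3/KITL control array, at 1.79, and Gzmc, Insig1, Id3 and Hmgcs1 without 4 or more of the arrays, at 1.77 to 2.38 for Gzmc and −1.02 to −0.50 for the other 3. In LLC medium 8 lost it without the IL-3 LLC array, at 1.48 to 2.34 for Ccl5, Gzmc and Il1b and −1.80 to −0.89 for Cyp51, Fdps, Hmgcs1, Mrgprb13 and Msmo1. Gzmc also lost it without either control, either MC38 or the IL-3/KITL LLC array, at 1.49 to 2.11, Fdps without the IL-3/KITL control or LLC array, at −0.92 and −1.23, and Cyp51 without the IL-3 control array, at −1.06. In MC38 medium 9 lost it without the IL-3/KITL MC38 array, at 1.0 to 1.52 for Ccl5, Pde7b and Procr and −0.98 to −0.58 for Dnase2b, Hmgcs1, Hsd17b7, Insig1, Msmo1 and Sqle. Without the IL-3 MC38 array, the IL-3 control array or the IL-3/KITL control array, 7, 6 and 8 of these 9 lost it. Their changes were 1.43 to 1.66 and −1.10 to −0.79 in the first of these fits, 1.08 and −1.08 to −0.69 in the second, and 1.07 to 1.15 and −0.97 to −0.68 in the third. Without either LLC array 4 lost it, at 1.59 and −0.97 to −0.69. Dnase2b lost it without any 1 array. Of the cholesterol synthesis genes, 0 or 1 fell in B16F10 medium without any 1 array. In LLC medium 1 fell without the IL-3 LLC array, 5 without the IL-3/KITL LLC array and 7 without either control array. In MC38 medium 1 fell without the IL-3 MC38 or control array and 0 without the IL-3/KITL MC38 or control array. Of the NF-kappaB targets, in B16F10 medium 1 rose without the IL-3/KITL control array, 2 without the IL-3/KITL B16F10 array and 3 without the IL-3 B16F10 or either LLC array. In LLC medium 0 rose without the IL-3 LLC array, 1 without the IL-3/KITL LLC array, 4 without either control array and 5 without either MC38 array. In MC38 medium 1 rose without either B16F10 array and 0 without any other array.

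The responses to the 3 media shared genes beyond what the number of calls alone gives. For B16F10 and LLC medium 76 genes rose in both, where 0.996 were expected from the counts, and for LLC and MC38 medium 43 rose and 9 fell in both, where 0.555 and 0.03 were expected. For B16F10 and MC38 medium 25 rose in both, where 0.194 were expected. No gene rose in 1 medium and fell in another among the limma calls, 24 rose in all 3 and 3 fell in all 3, and the union of the 3 held 342 genes. Because the 3 contrasts share the control arrays, 50 simulated sets of unchanged arrays with shared controls were compared with the data: the covariance of log2 changes across genes was 0.0184, 0.0124 and 0.0175 for B16F10 with LLC, B16F10 with MC38 and LLC with MC38, against 0.0051 in the simulations for each pair. Genes called in both numbered on average 0.06, 0.02 and 0.1 in the simulations. The simulated arrays had no medium effect, so these numbers are low by construction. They do not show how many real calls shared controls bring together. The correlations across genes were 0.640, 0.503 and 0.701, against 0.502 in the simulations, so the second did not exceed what shared controls give; genes are not independent replicates. Shared controls were avoided in a comparison added after the data were seen, of 1 medium in the IL-3 cells with another in the IL-3/KITL cells, each minus the control of its maturation. Over the 6 such combinations the correlation across 22180 genes lay between 0.119 and 0.294 and the covariance between 0.0050 and 0.0126. Each medium was also set against the mean of the other 3: the control differed in 263 genes, LLC medium in 31, B16F10 medium in 4 and MC38 medium in 3. For the control this is the comparison of conditioned with control medium with its sign turned, so its count is the same by construction.

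The conditioned media were compared with each other in the model of all 8 arrays, where the control arrays enter the error and the maturation term but not the compared means. By the limma F test 2 genes differed, Kcnma1 with adjusted p = 1.02e-05 and Cd68 with adjusted p = 0.0183, and 2006 genes had an unadjusted p under 0.05. Cd68 was 2.0-fold higher in LLC medium and 2.13-fold lower in B16F10 medium than in the mean of the other media. Kcnma1 was 78.2-fold higher in B16F10 medium. Genes with large differences that did not pass included Egln3 at 3.79-fold (adjusted p = 0.460) and Ak4 at 2.76-fold (0.641), both known to respond to low oxygen, and Bex6 at 2.70-fold (0.139) and H2bc12 at 2.29-fold (0.326), each with the higher level in B16F10 medium. Procr at 2.07-fold (0.125) and Plxna2 at 1.90-fold (0.130) had their lower level in B16F10 medium, and Pde7b at 1.81-fold (0.169) too. In LLC medium the estimates of Apol10a, Nlrp6, Hspa1b and F11r were 1.46-fold (F11r) to 1.56-fold (Apol10a) higher and those of Nox1, Mrgprb13 and Insig1 1.66-fold (Insig1) to 1.77-fold (Nox1) lower, with adjusted p-values from 0.125 (Nox1 and F11r) to 0.585 (Hspa1b). In MC38 medium Mrgpra9 was estimated 3.07-fold higher (0.130), Itgae 1.64-fold (0.212), Adamts5 1.61-fold (0.209) and Prss23 1.60-fold (0.461), and H2-Ab1 2.06-fold lower (0.559) and Bnip3 1.97-fold lower (0.619). The count was 4 without either control array or the IL-3 MC38 array, and 1 without the IL-3 B16F10, either LLC or the IL-3/KITL MC38 array. It was 1 when Kcnma1 was represented by its other probe set.

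Kcnma1 stood apart from every other gene in B16F10 medium. Its brighter probe set had an intensity of 9809 in the IL-3 and 8855 in the IL-3/KITL cells in B16F10 medium, against 54.8 to 145.3 in the other 6 arrays, and limma gave adjusted p = 2.99e-06 for the change from control. The control arrays, at 73.5 in the IL-3 and 54.8 in the IL-3/KITL cells, lay near the floor of 67.1. On the log2 scale the change was 7.06 in the IL-3 cells from their own control. In the IL-3/KITL cells it was at least 7.04, with the control taken at the floor. The other Kcnma1 probe set read 38.2 to 47.8 in all 8 arrays and changed by 0.10 ± 0.10 in B16F10 medium, so the 2 probe sets of the gene differed. The lower quartile of intensity of an array lay between 41.2 and 42.4, so the other probe set was near the floor in every array and does not show whether the transcript changed.

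**Figure D3:**
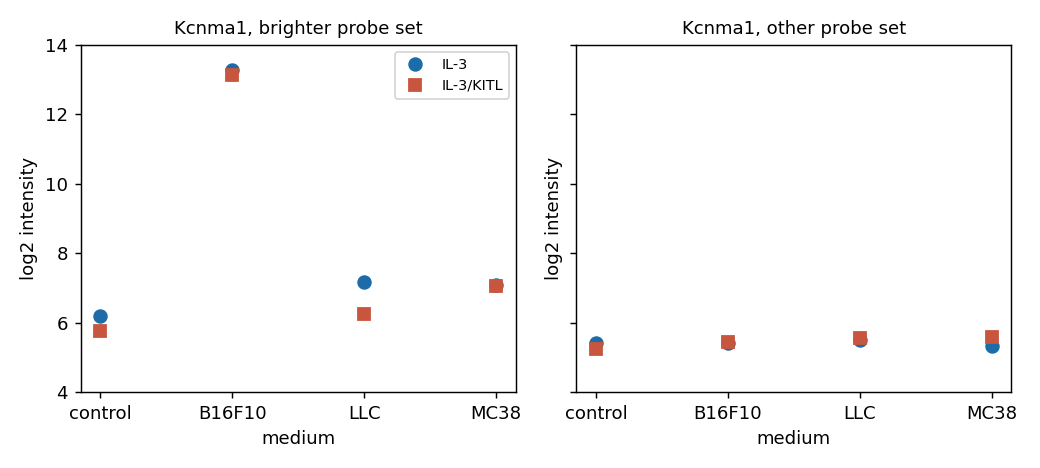
Log2 intensity per array (vertical axis) of the 2 probe sets of Kcnma1 by medium (horizontal axis), with 1 point per array and 1 colour per maturation. The brighter probe set read 13.26 and 13.11 in the B16F10 arrays and 5.78 to 7.18 elsewhere, and the other stayed between 5.26 and 5.58.

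Whether the response to conditioned medium differed between the maturations was tested as an interaction, which rests on 1 control array per maturation. No gene passed by limma, and 1379 had an unadjusted p under 0.05. For Ak4, the response in the IL-3/KITL cells minus that in the IL-3 cells was −3.39 ± 0.45 on the log2 scale, with adjusted p = 0.235. The estimates were −3.02 ± 0.47 for Egln3, a HIF prolyl hydroxylase (0.310), −2.10 ± 0.28 for Bnip3 (0.235), −1.86 ± 0.22 for the MHC class II gene H2-Ab1 (0.154) and −1.82 ± 0.16 for the mitochondrial gene ND6 (0.0515). On the other side were the mitotic genes Ccna2 at 1.73 ± 0.25 (0.267), Kif11 at 1.49 ± 0.29 (0.440), Nuf2 at 1.46 ± 0.31 (0.516), Ube2c at 1.43 ± 0.15 (0.133) and Anln at 1.34 ± 0.30 (0.583). The fit without either B16F10 array called 45 genes, these 10 among them, and the fit without either LLC array 1; without either MC38 array the count stayed 0, and without a control array the contrast cannot be fitted. Other settings of the full model called 0 to 24 genes.

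HIF targets and glycolysis genes on one side and G2/M genes on the other had opposite interaction estimates. Of 23 HIF targets, 20 had lower estimates, with a mean of −0.70, and of 19 glycolysis genes 17, with a mean of −0.49. All 35 G2/M genes had higher estimates, with a mean of 0.92. Over all genes tested none of the members passed by limma, and adjusted over the list alone 11, 8 and 27 did. The adjusted p-values with the preset correlation were 2.24e-17, 2.34e-12 and 9.43e-34, and the adjusted p with an estimated correlation was 0.587 for each of the 3 lists. In the IL-3 cells the median HIF target was 0.40, 0.23 and 0.08 above control in B16F10, LLC and MC38 medium, and in the IL-3/KITL cells the medians were −0.06, −0.49 and −0.47. The median G2/M gene was at 0.21, −0.72 and −0.74 in the IL-3 cells and at 0.64, 0.45 and 0.36 in the IL-3/KITL cells. The mean log2 level of the HIF targets was 8.70 in the IL-3 control array and 9.53 in the IL-3/KITL control array, and that of the G2/M genes 8.93 and 7.15, so the controls of the 2 maturations were far apart in both. Cholesterol synthesis genes showed no such difference between maturations: their medians were −0.33, −0.79 and −0.62 in the IL-3 cells and −0.39, −0.57 and −0.58 in the IL-3/KITL cells, and the interaction had a mean of 0.03 with adjusted p = 0.659, and adjusted p = 0.939 with an estimated correlation.

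Lists that passed in a single medium in 1 direction could turn with a control array. In B16F10 medium the G2/M genes had a mean change of 0.43, with 34 of 35 higher, 0 passing alone by limma and 0 when adjusted over the list alone (adjusted p = 8.44e-08, and adjusted p = 0.499 with an estimated correlation), and it was −0.03 without the IL-3/KITL control array. In MC38 medium the G2/M mean was −0.20 (adjusted p = 9.13e-04, and adjusted p = 0.779 with an estimated correlation) and 0.26 without the IL-3 control array, and it was 0.03 with adjusted p = 0.971 without the IL-3 MC38 array. HIF targets had a mean change of 0.21 in B16F10 medium (adjusted p = 0.0419, and adjusted p = 0.602 with an estimated correlation), which was −0.14 without the IL-3 control array and no longer passed without the IL-3 or the IL-3/KITL B16F10 array, at 0.23 and 0.19. In MC38 medium their mean was −0.26 (adjusted p = 0.0027, and adjusted p = 0.761 with an estimated correlation), which was 0.09 without the IL-3/KITL control array and −0.11 with adjusted p = 0.187 without the IL-3/KITL MC38 array. None of the 23 HIF targets passed alone by limma in either medium, over all genes tested or adjusted over the list alone.

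**Figure D4:**
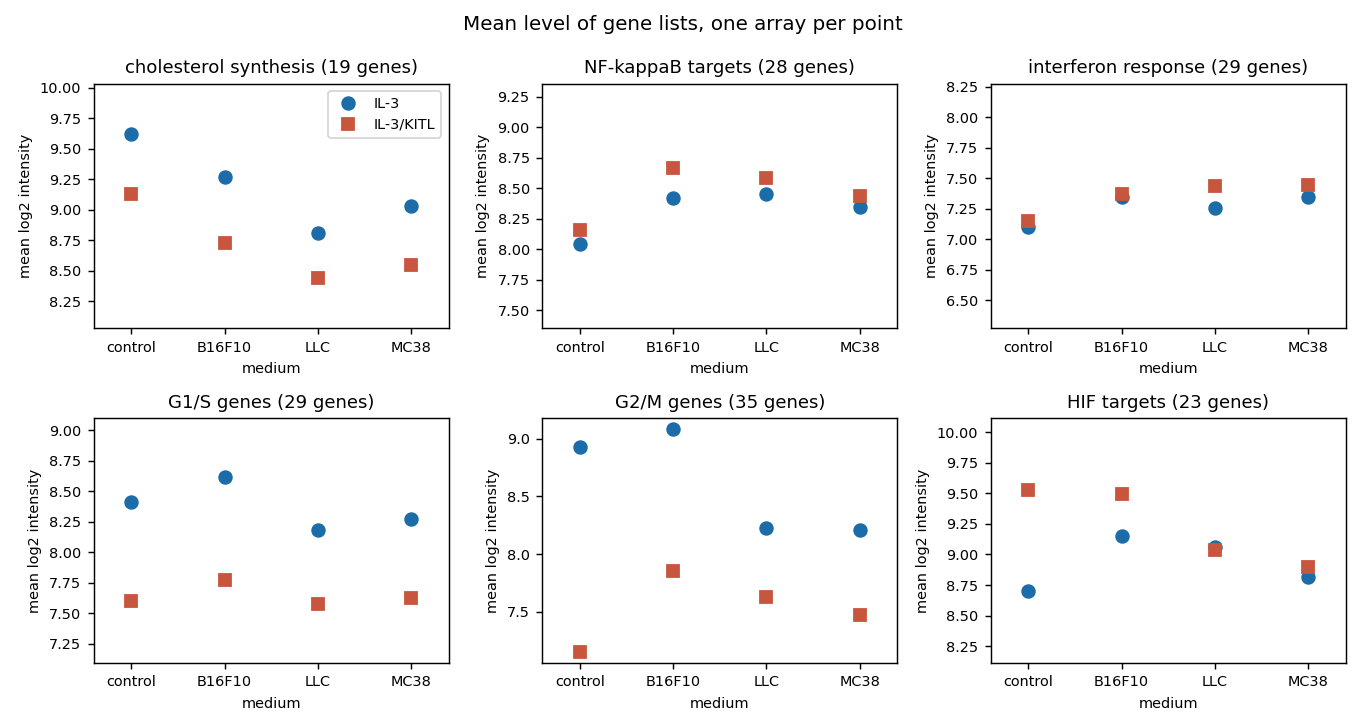
Mean log2 intensity per array (vertical axis) of the genes of fixed lists by medium (horizontal axis), with 1 point per array and 1 colour per maturation. The HIF target mean was 8.70 in the IL-3 and 9.53 in the IL-3/KITL control array, and the G2/M mean 8.93 and 7.15.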

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

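The tests of the IL-3/KITL control array and of culture density or oxygen were chosen only after the results they address had been seen. Several gene lists were picked out because their response to conditioned medium differed between the maturations in a test of the difference itself, with the preset correlation. These were HIF targets at −0.70, glycolysis at −0.49 and G2/M genes at 0.92 on the log2 scale, conditioned minus control in IL-3/KITL minus the same in IL-3 cells. Smaller differences were those of basophil markers at −0.35, eosinophil markers at −0.21, ribosomal proteins at −0.16, ATF4 and amino acid response genes at 0.13 and pattern recognition receptors at −0.13. No list passed with an estimated correlation, whose smallest adjusted p was 0.587. The calls of the ATF4 genes, the eosinophil markers and the pattern recognition receptors ended in at least 1 fit with an array left out. Probe sets without a single gene symbol were picked out because they carry signal that the gene comparisons do not use: of 10273, 187 differed between maturations, 96 higher and 91 lower in IL-3/KITL cells, and 6 between conditioned and control medium, 3 higher and 3 lower.

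The opposite HIF and G2/M differences rest on 1 control array per maturation. Whether the IL-3/KITL control array alone was out of line stays open, since these cells have no other control array. In them B16F10 medium exceeded the mean of LLC and MC38 medium by 0.53 over the HIF targets, but this does not bear on the control array, because the media had the same order in the IL-3 cells, with means of 9.15, 9.06 and 8.81. Culture density or oxygen at harvest was taken to move the HIF and G2/M genes against each other. Over the 8 arrays, as deviations from the maturation means, their means had r = 0.0073 (permutation p = 0.986) and Spearman's rho = 0.0952 (permutation p = 0.840). This was 1 relation computed, with r = 0.214 without the 2 arrays farthest from the median. The permutations moved deviations across maturations, so these p-values are approximate. With 8 arrays, the relation does not decide the question. The explanation cannot be told apart from a difference in response between the maturations, the biological explanation, which stays open. That difference was tested as an interaction and neither list passed with an estimated correlation, where 2 residual degrees of freedom leave little power. The maturation as its cause is untested.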

How the results depend on the processing

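The fits without both B16F10 arrays, with the HIF target mean as a covariate, with the other Kcnma1 probe set and without the genes of the cell cycle or cholesterol lists were chosen after the data had been seen. Of the values for named genes 1384 kept direction and side of the threshold, 234 lost and 37 gained the threshold and 0 reversed; of the list values 705 kept both, 268 lost the threshold and 7 reversed; of the counts 48 stayed within 1.5 times and 77 moved. With each array left out in turn, the counts ranged from 1095 to 1561 for maturation, 44 to 169 for conditioned medium, 10 to 74 for B16F10, 11 to 215 for LLC, 3 to 47 for MC38, 1 to 4 between conditioned media and 0 to 45 for the interaction, where the fit without either control array could not be run; fewer arrays are part of the cause. Quantile normalization gave 52 for B16F10 and 3 for the interaction, median centring 157 and 16, and probe sets above the 40th percentile 172 and 3. With trend and robust the counts were 395 for conditioned medium, 207 for B16F10, 495 for LLC, 114 for MC38, 31 between media and 24 for the interaction. The mean of probe sets and array weights each gave 3 for the interaction. A change of at least 1 left 109 for maturation, 20 for conditioned medium, 20 for B16F10, 41 for LLC and 15 for MC38, by construction. An adjusted p under 0.1 gave 467 for conditioned medium, 238 for B16F10, 565 for LLC, 102 for MC38 and 3 for the interaction, also by construction. Maturation had 1432 without a medium term, 1149 without both B16F10 arrays and 1144 with the HIF covariate. Conditioned medium had 50 with 2 levels of medium, 14 without a maturation term, and 1 in the IL-3 arrays alone and 1 in the IL-3/KITL arrays alone. These 2 fits set 1 control array, assumed to vary like the others, against 3 media taken as replicates, so genes that differ between media fail by construction, and they say nothing about stability. Each holds 27 of the 234 lost calls. Between media 1 gene passed with the other Kcnma1 probe set, which by construction removes Kcnma1. Some list means reversed when a control array was left out, and their ranges over all arrays left out were, in B16F10 medium, −0.1385 to 0.5603 for HIF targets, −0.021 to 0.4723 for glycolysis and −0.0315 to 0.8877 for G2/M genes, and in MC38 medium −0.6083 to 0.0906 for HIF targets, −0.4173 to 0.076 for glycolysis and −0.6635 to 0.2557 for G2/M genes. With the HIF covariate, glycolysis reversed in MC38 medium at 0.0122. Where no cause is named, the cause was not tested. Signal over background limits the changes that dim genes can show, since the smallest intensities were 18.0 to 18.4.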

Other observations

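The tests of 1 RNA species of B16F10 medium, of the whole Kcnma1 transcript and of FOXO targets were chosen only after the results they address had been seen. Beyond the groups described so far, single regulators of cell death and lipid handling differed between the maturations, while neither list passed. Of 18 apoptosis regulators 3 rose and 3 fell in the IL-3/KITL cells, and 5 rose and 3 fell when adjusted over the list alone: Bcl2l11 changed by 1.11 ± 0.10, the survival gene Bcl2 by −0.55 ± 0.06 and Birc3 by 0.51 ± 0.05. For this list the test gave adjusted p = 0.271, and adjusted p = 0.460 with an estimated correlation, and the number that fell was 1 without either control, LLC or MC38 array, while 2 rose without either control, B16F10 or LLC array. Of 15 lipid efflux and LXR targets 3 rose and 0 fell in every fit, among them Lpl at 0.59 ± 0.08, Mylip at 0.39 ± 0.06 and Abca1, a cholesterol exporter, at 0.37 ± 0.07. Adjusted over the list alone 3 rose and 2 fell, the median was −0.02 against a mean of 0.07, and the list had adjusted p = 0.669, and adjusted p = 0.789 with an estimated correlation. Of 21 genes of the unfolded protein response 4 fell and 1 rose, with Sdf2l1 at −0.82 ± 0.08 and the chaperone Calr at −0.44 ± 0.06, and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 6.27e-04, and adjusted p = 0.457 with an estimated correlation). Without any 1 array 2 of them fell and 0 rose by limma.

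In conditioned medium, 3 of 20 genes of lipid mediator synthesis rose and 0 fell, and 3 rose when adjusted over the list alone, with Ptgs2, the inducible cyclooxygenase, at 0.61 ± 0.07 and Ptgr1 at 0.65 ± 0.10. The list had adjusted p = 0.0480, and adjusted p = 0.349 with an estimated correlation, and no longer passed without the IL-3 control array (0.132), the IL-3 B16F10 array (0.0745) or the IL-3/KITL MC38 array (0.0645). Ptgs2 lost its call without either control array, at 0.53 to 0.68, and Ptgr1 without these, the IL-3 B16F10 or the IL-3/KITL MC38 array, at 0.50 to 0.80. Pla2g7, the other gene that rose, lost its call whichever of the 8 arrays was left out, at 0.40 to 0.47. Of 13 MHC class II genes 3 rose and 0 fell, the same 3 when adjusted over the list alone, with H2-Oa at 0.84 ± 0.11, which lost its call without either control array, at 0.73 to 0.96. The other risen genes were less stable: H2-DMa lost its call without 6 of the arrays, at 0.41 to 0.52, and H2-Ob without 7, at 0.325 to 0.755. That list had adjusted p = 0.0032, adjusted p = 0.292 with an estimated correlation, and adjusted p = 0.183 without the IL-3 control array, where 0 rose by limma. The tetraspanin gene Cd81 rose by 0.78 ± 0.07 and the TGF-beta-induced repressor Klf10 by 0.91 ± 0.07, and both kept their call without any 1 array.

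Chance was tested as a source of the maturation count. Of the 35 splits of the 8 arrays into 4 and 4, fitted without a medium term, 1, the real one, gave as many genes, 1432 against at most 1 in any other split. This share of 1 in 35 lies under 0.05 and is the smallest that the test can give. The other splits mix the maturations, so a maturation difference enters their error and lowers their counts. The test therefore argues against chance in how the arrays were grouped but does not exclude it. With the medium term, the splits that keep each medium as a pair number 8, too few for a share under 0.05, and gave 2213 for the real one and 0 for the others. No split tests a chance difference between 2 cultures, since nothing says that the arrays of a maturation came from separate cultures.

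For the Kcnma1 probe set in B16F10 medium, 11 melanocyte pigment genes had a mean change of −0.0339 ± 0.026 (SE over genes), at a mean log2 level of 5.86. This argues against carry-over of total RNA from B16F10 cells in an amount that would raise these genes. Because their probe sets were dim, a smaller carry-over is not excluded. Induction of the whole Kcnma1 transcript stays open: the other probe set changed by 0.10 ± 0.10, but its highest intensity was 47.8, below the 40th percentile of probe sets, so it may not detect the transcript at all. One RNA species of the B16F10 medium read by this probe set stays open: 0 other probe sets lay at least 1 above every other array in both B16F10 arrays, and the next largest gap was 0.75. B16 cells are known to release endogenous retroviral particles, and the sequences of the probes, which were not used here, could test whether this probe set reads such RNA. An isoform of Kcnma1 read by 1 probe set alone was not tested.

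For the lower cell cycle genes in IL-3/KITL cells, fewer cycling cells of other blood types stay open. The 16 markers of other blood cells with a log2 level of at least 8 in IL-3 cells changed by −0.54 ± 0.156 (SE over markers) on average, 8 fell and 0 rose, against −1.09 for G2/M genes. Choosing markers by their level in the IL-3 arrays alone favours a fall. The arrays also do not show which cells express these markers. Higher FOXO activity, a brake on the cell cycle that growth factor signalling restrains, stays open as well. Of 27 measured FOXO targets, a list that excludes Il7r, Bcl6 and Bcl2l11, 14 rose and 0 fell, with a mean change of 0.22, p = 5.53e-07 in limma's camera with the preset correlation and p = 0.0633 with an estimated correlation. The 2 explanations cannot be told apart from each other or from a slower cycle of the mast cells themselves, because the arrays measure whole cultures. The maturation itself, the biological explanation in the design, stays open and is untested as the cause.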
